A study of Mus musculus with 9 samples.

How the data were processed

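Transcripts were measured on 9 Affymetrix 3-prime expression arrays hybridised with biotin-labelled cRNA, 3 arrays in each of 3 groups. Per the labels, retinal progenitor cells derived from mouse embryonic stem cells (ESC-RPCs) came from embryoid bodies formed over 3 days, from which Sox1-positive cells (35.8%) were sorted at day 7. The sorted cells were then cultured with 10 µM DAPT, an inhibitor of Notch processing, and 20 ng/ml basic fibroblast growth factor. One group of ESC-RPCs received 1 ng/ml recombinant DKK1, a secreted Wnt antagonist, for 1 day, and a second group received none. Primary retinal progenitor cells came from dissociated neural retina of C57 mice on postnatal day 1.

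The deposited values are intensity values in linear units, 1 per probe set and array, which the authors made with MAS5 according to their processing notes. The notes name no software version or settings. In each of the 9 deposited columns the mean after trimming 2% of probe sets at either end was 500, so each array had been scaled to that mean, and no value lay below 1. Arrays give no read depth, and the number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.15.

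The table held 45101 probe sets. The 64 control probe sets were set aside, 932 probe sets matched several genes, and 9160 were listed with no gene. Log2 was taken of each value, and no further normalisation was applied. A probe set was kept if it lay above its own array's 40th percentile on at least 3 of the 9 arrays, which left 29052, of which 24773 had exactly 1 gene. Each gene was represented by the kept probe set with the highest mean log2 value over all 9 arrays, which gave 13320 genes. No genome build was named in the labels, so no coordinates are given.

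A linear model per gene was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend in the empirical Bayes step and no further covariate. The 3 pairs of groups were compared with two-sided moderated tests, and p-values were adjusted over all genes by the Benjamini-Hochberg method, with genes called at an adjusted p below 0.05. Of 37 gene lists written from textbook function, the 35 with at least 5 measured genes were tested with camera in limma, at its preset inter-gene correlation of 0.01. Their p-values were adjusted over the lists within each comparison. Camera compares the genes of a list with all other genes, and each call was also tested with the correlation estimated from the data and with fry, a rotation test in limma of whether a list moves one way. The distance of an ESC-RPC array to the primary profile was the root mean square log2 difference from the mean of the 3 primary arrays, tested by a two-sided exact permutation test.

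The groups, tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named, for each comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, passing over transcripts without a gene name. It added up to 4 members with the smallest adjusted p for each list described, and always a fixed set of genes that included Dkk1, Axin2, Lef1, Ccnd1, Myc, Mki67, Sox1, Nes, Pax6, Rax, Six3, Six6 and Crx. Where all 3 arrays of a group lay below their own 40th percentile, a fold change was computed against those percentiles and is printed as "at least", and list medians are also given with such genes at that bound.

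Both ESC-RPC groups carried replicate numbers 1 to 3. For each pair of arrays with the same number, deviations from the group means were correlated across genes, which are not independent replicates. The same-number correlations between DKK1-treated and untreated arrays were 0.123, 0.195 and 0.318, and those between different numbers were -0.234 to 0.0681. All 3 same-number values exceeded 0.1, so the numbers were taken to pair these arrays. With 3 arrays per group few matchings are possible, so these values do not settle the pairing. This pairing comes from the values and is not stated in the labels. The same-number correlations with the primary arrays lay between -0.0433 and -2.36e-06, so the primary arrays were not paired. The planned fit with the replicate number as a block covered all 9 arrays. A blocked fit of the 6 ESC-RPC arrays alone was chosen after seeing the data, since only those arrays were taken as paired.

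Recovery was tested on simulated data with changes in 200 of 13320 genes. In the comparison of DKK1-treated with untreated cells, the fit of 9 arrays recovered 17.9% of changes of 0.5, 56.7% of changes of 1 and 83.3% of changes of 2 on the log2 scale, with 4 false calls among 109. The blocked fit of 6 arrays was run on other simulated data, with a pair effect built in and its own residual spread as noise. That fit recovered 37.3%, 55.2% and 80.3% of changes of these sizes, so the recoveries of the 2 fits cannot be compared. A list shifted by -0.25 in log2 was called by camera in 19 of 20 simulations, and 6 of 680 tests of unshifted lists were called. The simulated noise was independent between genes, so these counts do not cover lists of correlated genes.

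The alternatives were quantile normalisation, arrays set to one median, log2 after adding 32, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, tests per probe set, a 2-fold threshold, no intensity trend, the replicate block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.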

Results

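Gene expression was measured in 3 groups of 3 mouse arrays: ESC-RPCs treated with DKK1, untreated ESC-RPCs, and primary retinal progenitor cells (RPCs) from newborn retina. The labels name the ESC-RPCs as retinal progenitors derived from embryonic stem cells, and that identity was not tested here. The series describes the untreated cells as an early stage, the DKK1-treated cells as a later stage, and the primary cells as a negative control for proliferation and oncogenesis. Values are MAS5 intensities, given as mean ± SD (n = 3 arrays per group), and log2 differences are given ± SE from limma. Across genes, which are not independent replicates, log2 profiles correlated at 0.975 to 0.985 between DKK1-treated and untreated arrays. The correlations were 0.825 to 0.836 between ESC-RPC and primary arrays and 0.964 to 0.977 among primary arrays. The 3-prime over 5-prime signal ratio, a measure of RNA integrity, was 1.35 ± 0.0184, 1.34 ± 0.0251 and 1.24 ± 0.0219 for Actb in DKK1-treated, untreated and primary cells. For Gapdh it was 0.779 ± 0.0181, 0.763 ± 0.0208 and 0.742 ± 0.0161.

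The first comparison asked what 1 day of DKK1 did to ESC-RPCs. Of 14 measured feedback targets of Wnt signalling, 12 had lower mean intensities after DKK1, but none passed the test in the fit of 9 arrays. As a list they were called by camera (adjusted p = 0.000298; adjusted p = 0.637 with an estimated correlation). Nkd1, an intracellular Wnt inhibitor, measured 509 ± 78.6 in treated against 841 ± 7.38 in untreated cells. Axin2, a negative feedback regulator of the pathway, measured 608 ± 39.7 against 791 ± 34.1. Lef1, a transcription factor that binds beta-catenin, measured 744 ± 37.6 against 1089 ± 165. Hoxb1, a hindbrain homeobox gene, measured 221 ± 90.5 against 400.2 ± 46.7, and the eye field gene Six3 measured 1534 ± 640 against 1054 ± 435.

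In the limma fit of 9 arrays, 0 of 13320 genes changed, with 308 at an unadjusted p under 0.05 and a smallest adjusted p of 0.976. The planned replicate block on all 9 arrays also gave 0 genes. The blocked fit of the 6 ESC-RPC arrays, chosen after seeing the data, gave 65 genes, 29 higher and 36 lower, with 2001 at an unadjusted p under 0.05. The groups did not overlap for 1594 genes, or 11.97%, where chance gives 10% if the arrays are not paired. The 65 calls numbered 8 without replicate 2 and 213 without replicate 3, 0 when each gene's probe sets were averaged, and 0 without the intensity trend. Quantile normalisation gave 32 and no filter gave 21, and with arrays set to one median the split was 15 higher and 33 lower.

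Among those 65 genes, 37 had names and groups that did not overlap, 9 higher and 28 lower. In this blocked limma fit Nkd1 fell by 0.74 on the log2 scale (SE 0.09, adjusted p = 0.00929), Lef1 fell by 0.54 (SE 0.07, adjusted p = 0.0138) and Axin2 fell by 0.38 (SE 0.07, adjusted p = 0.04999). Hoxb1 showed the largest fall among them, 400.2 to 221 in intensity (log2 difference -0.93 ± 0.16). Abcd2, a peroxisomal fatty acid transporter, fell by 0.80 ± 0.11, Tnfrsf19 fell by 0.76 ± 0.06 and Rgl2 fell by 0.66 ± 0.08. Pax3, a dorsal neural tube gene, fell by 0.61 ± 0.06, and Crabp2, a retinoic acid binding protein, fell by 0.56 ± 0.06. The largest rises were those of Mreg (0.58 ± 0.07), Tdgf1 (0.57 ± 0.08), Dhtkd1 (0.56 ± 0.10) and Nr0b1 (0.54 ± 0.08), followed by Zfp42 (0.41 ± 0.06), Upp1 (0.38 ± 0.06), Zfas1 (0.34 ± 0.05) and Lrig1 (0.22 ± 0.04). Tdgf1, Nr0b1 and Zfp42 are stem cell genes. Six3, whose groups overlapped, rose by 0.53 ± 0.06 in the paired values (adjusted p = 0.00602). Of the 21 retinal progenitor genes, Six3 was the 1 that rose and Fgf15 the 1 that fell in this fit; 10 were higher and 11 lower (median -0.05, camera adjusted p = 0.98 in the fit of 9 arrays).

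Camera in limma called 8 of 35 gene lists between DKK1-treated and untreated cells, 5 lower and 3 higher, and 0 with an estimated correlation or by fry. In each of these 8 lists no member changed in the fit of 9 arrays when adjusted over all genes. Of 14 measured Wnt feedback targets, 12 had lower intensities after DKK1, and 8 were lower in all 3 pairs of arrays (list median -0.23, adjusted p = 0.000298). The adjusted p was 0.637 with an estimated correlation, and the median was -0.12 without DKK1-treated replicate 2 and -0.13 without untreated replicate 3. In the fit of 9 arrays 2 members, Nkd1 and Axin2, fell when adjusted over the list alone, against 0 in the other 7 called lists. Among lists that camera did not call, 2 of 6 lens markers (Crybb2 and Lim2) and 1 of 11 proneural genes (Hes6) fell, and 1 of 14 immediate early genes (Junb) rose, adjusted over the list alone. Dkk1 itself measured 128 ± 23.9 against 134 ± 16.9, Myc 561 ± 10.0 against 657 ± 71.7, and Ccnd1 3711 ± 698 against 3980 ± 555. The 34 measured components of the Wnt pathway, such as Axin1 (477 ± 86.1 against 580.1 ± 64.7) and Fzd5 (256 ± 50.3 against 205 ± 0.231), had a list median of 0.00 (adjusted p = 0.98).

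**Figure D1:**
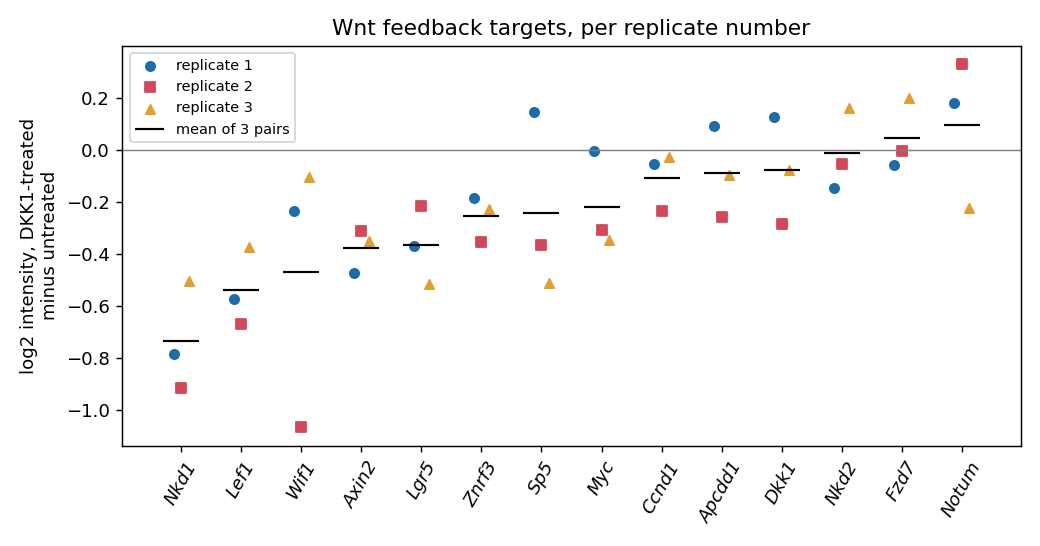
Log2 intensity of each of the 14 measured Wnt feedback targets in DKK1-treated minus untreated ESC-RPCs, for the 3 pairs of arrays with the same replicate number (points) and their mean (lines). Of the 14 targets, 8 lie below 0 in all 3 pairs.

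All 12 measured midbrain, hindbrain and spinal genes had lower intensities after DKK1 (median -0.42, adjusted p = 0.000549 by camera; adjusted p = 0.38 with an estimated correlation). The median was -0.27 without untreated replicate 3. Gbx2 measured 219.6 ± 56.0 against 319 ± 67.9 and Hoxa5 98.1 ± 16.9 against 139 ± 22.8. Camera did not call the list of forebrain genes in this comparison. Of 34 mitosis genes, 31 were lower (median -0.11, adjusted p = 0.000298; adjusted p = 0.784 with an estimated correlation), among them Top2a at 7811 ± 682 against 8678 ± 538. The mitosis call was lost without DKK1-treated replicate 2 (median -0.00479, adjusted p = 0.988) and without untreated replicate 3 (median -0.05, adjusted p = 0.339), and the median was -0.19 without DKK1-treated replicate 3. The proliferation marker Mki67 measured 3885 ± 582 against 4116 ± 343. Of 34 DNA replication genes, 28 were lower (median -0.10, adjusted p = 0.0187; adjusted p = 0.842 with an estimated correlation), such as Rrm1 at 3380.2 ± 445 against 3751 ± 246. Without DKK1-treated replicate 2, camera turned the direction of this list (median -0.01, adjusted p = 0.988). Its median was -0.04 without untreated replicate 3, which ended the call (adjusted p = 0.809), and -0.18 without DKK1-treated replicate 3. All 16 cholesterol synthesis genes were lower (median -0.12, adjusted p = 0.00956; adjusted p = 0.784 with an estimated correlation), such as Sqle at 4911 ± 146 against 5633 ± 344. That call was lost without DKK1-treated replicate 1 (median -0.11, adjusted p = 0.0575).

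The 3 lists called higher held small differences. Of 23 pluripotency genes, 19 were higher after DKK1 (median 0.15, adjusted p = 0.0187 by camera; adjusted p = 0.637 with an estimated correlation), such as Dppa4 at 948 ± 36.7 against 763 ± 33.5 and Gdf3 at 593 ± 68.0 against 475 ± 49.6. Of 16 Müller glia genes, 13 were higher (median 0.15, adjusted p = 0.0187; adjusted p = 0.38 with an estimated correlation), such as Clu at 1512 ± 9.52 against 1311 ± 74.8. Of 9 endoderm and mesoderm markers, 8 were higher (median 0.33, or 0.16 with dim genes at their bounds, adjusted p = 0.0187; adjusted p = 0.637 with an estimated correlation). Some were near background, such as Mesp1 at 67.2 ± 17.9 against 46.1 ± 4.85. Leaving out 1 array ended each of these 3 calls: pluripotency without DKK1-treated replicate 1 (median 0.10), DKK1-treated replicate 3 (0.14) or untreated replicate 2 (0.06), and Müller glia without DKK1-treated replicate 1 (0.08), untreated replicate 2 (0.14) or untreated replicate 3 (0.10). For the endoderm and mesoderm markers it was DKK1-treated replicate 3 (0.09) or untreated replicate 2 (0.10). With the replicate block on 6 arrays, chosen after seeing the data, the 8 lists were called with adjusted p-values of 0.0268 or less. With an estimated correlation in that fit their adjusted p-values were 0.526 to 0.701. General neural progenitor genes (17 measured, median -0.08, blocked adjusted p = 0.0331; adjusted p = 0.526 with an estimated correlation) and glycolysis genes (16 measured, median 0.05, blocked adjusted p = 0.0411; adjusted p = 0.82 with an estimated correlation) were then called as well. The 8 list calls numbered 5 without DKK1-treated replicate 1, 14 without DKK1-treated replicate 3, 5 without untreated replicate 2 and 5 without untreated replicate 3, and 5 with the mean of a gene's probe sets.

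Retinal markers did not pass the test between the ESC-RPC groups in the fit of 9 arrays, in which 0 of 13320 genes passed. Pax6 measured 1255 ± 210.5 against 1323 ± 193, Six6 63.2 ± 27.7 against 46.0 ± 12.9, Rax 12.5 ± 16.0 against 28.2 ± 21.4 and Crx 8.29 ± 4.60 against 18.97 ± 16.9. The 40th percentiles of the ESC-RPC arrays were 45.6 to 47.7. Crx lay below them on every array of both groups, and the means of Rax and Six6 lay below or near them. For these genes the test compared values near background. Sox1 measured 2886 ± 333 against 2831 ± 59.8, and Nes 840.4 ± 162 against 1026 ± 178. The distance to the primary profile was 1.29 ± 0.00361 in DKK1-treated and 1.28 ± 0.0159 in untreated cells (n = 3 each). The difference of 0.00923 gave an exact two-sided permutation p of 0.4, where the smallest p that 20 relabelings can give is 0.1. The difference was 0.00257 without untreated replicate 2 and 0.018 without untreated replicate 3. The distance was lower in the treated array of 1 of 3 pairs.

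The second comparison set untreated ESC-RPCs against primary RPCs, the series' negative control for proliferation and oncogenesis. Of the pluripotency genes measured most were higher in ESC-RPCs, and of the photoreceptor genes most were lower. Nanog, a core transcription factor of embryonic stem cells, measured 2103 ± 299 against 2.35 ± 0.558, at least 44.1-fold higher. Zfp42, a stem cell zinc finger gene, was at least 60.6-fold higher at 2903 ± 515. Crx, a transcription factor of photoreceptor precursors, was at least 92.3-fold lower, at 18.97 ± 16.9 against 4478 ± 1461. Pax6 measured 1323 ± 193 against 10035 ± 1063 (log2 difference -2.93 ± 0.14).

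Of 23 pluripotency genes, 21 rose in untreated ESC-RPCs and 1 fell (median 4.51, or 3.30 with dim genes at their bounds, camera adjusted p = 1.04e-11; adjusted p = 0.0742 with an estimated correlation). Dppa5a measured 10411 ± 1243 against 129.8 ± 21.8, Dppa4 was at least 16.1-fold higher, and Tdgf1 at least 13.2-fold higher. Further large rises were those of S100g (at least 24.7-fold), Morc1 (at least 15.6-fold), Serpinb1a (at least 23.6-fold), Pou3f4 (at least 39.0-fold) and Trap1a (at least 30.6-fold). Of 17 general neural progenitor genes, 7 rose, 5 fell and 5 did not pass the test (camera adjusted p = 0.495). Sox1, on which the cells were sorted, was at least 59.8-fold higher, and Nes rose from 564 ± 290.1 to 1026 ± 178 (adjusted p = 0.0275). Of 12 midbrain, hindbrain and spinal genes, 9 rose and 1 fell (median 2.82, or 1.61 with bounds, adjusted p = 9.57e-05; adjusted p = 0.0742 with an estimated correlation). En2, a midbrain and hindbrain gene, was at least 34.5-fold higher at 1639 ± 163, and Hoxb2 at least 18.7-fold higher at 899.6 ± 212. Forebrain genes went both ways, and camera did not call their list. Otx1 was at least 19.1-fold and Dlx5 at least 10.8-fold higher, and Dlx1, Dlx2, Emx2 and Gsx2 rose too. Eomes, Fezf2 and Otx2 fell, and Tbr1 did not pass the test.

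Of 24 photoreceptor genes, 21 fell in untreated ESC-RPCs and 3 did not pass the test (median -3.84, or -3.23 with bounds, adjusted p = 1.93e-10; adjusted p = 0.0742 with an estimated correlation). Prdm1 fell from 5288 ± 1407 to 89.8 ± 12.5, Neurod1 fell from 16847 ± 1667 to 1449 ± 182, and Sag, rod arrestin, was at least 37.7-fold lower. Pdc, a photoreceptor phosphoprotein, was at least 172-fold lower and Rp1 at least 7.56-fold lower. Of 21 retinal progenitor genes, 16 fell and 3 rose (median -2.17, adjusted p = 2.15e-05; adjusted p = 0.0742 with an estimated correlation). Six6 measured 46.0 ± 12.9 against 4386 ± 440.3, Rax 28.2 ± 21.4 against 3939 ± 943, Six3 1054 ± 435 against 6896 ± 488, and Aldh1a1 was at least 65.1-fold lower. Dapl1 was at least 123-fold lower, Hmx1 at least 46.3-fold lower, and Xist fell from 11668 ± 1030.2 to 68.1 ± 18.2. Of 11 proneural genes, 8 fell (median -1.31, adjusted p = 0.000909; adjusted p = 0.197 with an estimated correlation), among them Atoh7, which specifies ganglion cells, at 59.1 ± 17.3 against 3998 ± 1078. Of 10 bipolar cell genes, 7 fell (median -1.53, adjusted p = 0.0156; adjusted p = 0.127 with an estimated correlation), such as Otx2, at 5470.01 ± 689 against 15492 ± 3009. Otx2 is also on the photoreceptor and forebrain lists, and Isl1, which fell too, on the ganglion cell list, so these lists are not independent.

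**Figure D2:**
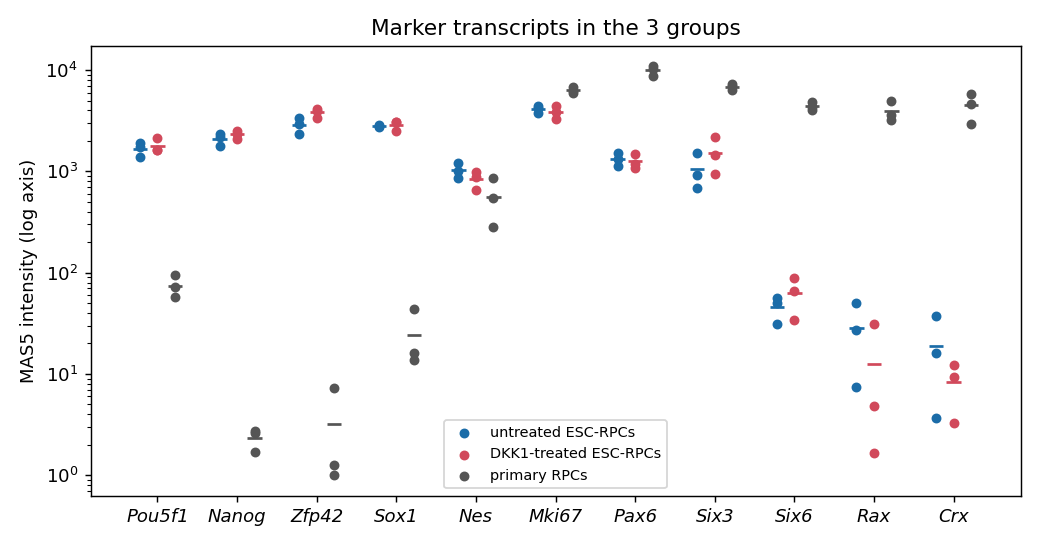
MAS5 intensity (log axis) of marker transcripts on each array of the 3 groups (points), with group means. Nanog has means of 2331 and 2103 in the ESC-RPC groups and 2.35 in primary RPCs, and Crx means of 8.29, 18.97 and 4478 in DKK1-treated, untreated and primary cells.

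Markers of other cell types moved with the group. Of 15 mesenchyme markers, 13 rose in untreated ESC-RPCs (median 3.32, adjusted p = 4.80e-08; adjusted p = 0.197 with an estimated correlation), such as Col3a1, a fibrillar collagen, from 41.5 ± 17.1 to 8541 ± 796 and Dcn from 51.1 ± 12.6 to 3878 ± 487. All 5 measured astrocyte markers rose (median 4.74, adjusted p = 3.09e-05; adjusted p = 0.0742 with an estimated correlation), such as Gja1 from 348 ± 10.2 to 9295 ± 352 and Aldoc from 216 ± 47.1 to 7944 ± 1187. Of 10 microglia and macrophage markers, 5 fell (median -1.31, adjusted p = 0.0076; adjusted p = 0.304 with an estimated correlation), such as Ctss, at least 9.52-fold lower, and C1qb, at least 3.74-fold lower. Of 14 immediate early genes, which respond to stimulation within minutes, 12 fell (median -1.25, adjusted p = 0.000395; adjusted p = 0.0742 with an estimated correlation), such as Fos from 4150.5 ± 1538 to 299.7 ± 66.8 and Egr1 from 5798 ± 624 to 542 ± 90.1.

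Wnt genes and cholesterol synthesis genes had higher intensities in untreated ESC-RPCs than in primary cells. Of 14 Wnt feedback targets, 11 rose and 2 fell (median 1.30, adjusted p = 0.00105; adjusted p = 0.304 with an estimated correlation). Axin2 rose from 245 ± 21.7 to 791 ± 34.1, Lef1 from 508 ± 300.3 to 1089 ± 165 and Myc from 261 ± 69.5 to 657 ± 71.7, while Ccnd1 fell from 12525 ± 2968 to 3980 ± 555. Dkk1 was at least 2.82-fold higher. Of 34 Wnt pathway components, 20 rose and 7 fell (median 0.70, adjusted p = 0.00185; adjusted p = 0.0742 with an estimated correlation), with Wnt5a up from 169 ± 34.8 to 1143 ± 118 and the retinal receptor Fzd5 down from 5167 ± 707 to 205 ± 0.231. All 16 cholesterol synthesis genes rose (median 1.66, adjusted p = 5.51e-09; adjusted p = 0.257 with an estimated correlation), such as Lss by 1.84 ± 0.11 and Fdps by 1.98 ± 0.12 in log2. Of 16 imprinted genes, 9 rose and 3 fell (median 0.45, adjusted p = 0.0341; adjusted p = 0.154 with an estimated correlation), such as Peg3 from 2646 ± 509 to 7156 ± 414, while Grb10 fell from 7992 ± 549.96 to 911 ± 41.4.

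Cell cycle and oncogene lists went both ways. Of 34 DNA replication genes, 13 rose and 1 fell (median 0.38, adjusted p = 0.0101; adjusted p = 0.661 with an estimated correlation), such as Ccne1 from 394 ± 101 to 695 ± 76.6. This call was lost without primary replicate 1 (median 0.39, adjusted p = 0.0628) and without primary replicate 3 (median 0.22, adjusted p = 0.0997). Of 34 mitosis genes, 4 rose and 9 fell (adjusted p = 0.324), and Mki67 fell from 6349 ± 412 to 4116 ± 343. Of 27 proto-oncogenes and oncofetal genes, 10 rose and 10 fell (adjusted p = 0.859). Sall4 was at least 32.4-fold higher and Lin28a at least 16.0-fold higher, while Myb fell from 10493 ± 1143 to 233 ± 38.9 and Fos fell as given above. Of 13 cell cycle brakes, 3 rose and 8 fell (adjusted p = 0.305), with Cdkn2a, which encodes p16 and p19, up from 95.0 ± 22.8 to 1029 ± 114 and Cdkn1a down from 2849 ± 311 to 1029.7 ± 105.

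In limma, 7060 of 13320 genes (53.003%) changed between untreated ESC-RPCs and primary cells, 3482 higher and 3578 lower, and 2770 of them by at least 2-fold. With arrays set to one median the balance turned, to 3657 higher and 2907 lower. Camera called 15 of 35 lists, 9 higher and 6 lower, 0 with an estimated correlation, while fry called 27. Adjusted over the list alone, the counts were the same for most lists given above. The exceptions were 22 photoreceptor genes lower, 11 midbrain, hindbrain and spinal genes higher, 21 Wnt pathway components higher, 10 imprinted genes higher, 4 cell cycle brakes higher, 11 proto-oncogenes higher and 0 DNA replication genes lower. Cell origin, genetic background and culture differed together between these groups, as did the Actb signal ratio and the intensities of Xist and Y-linked genes. For 203 of 3587 called genes with several kept probe sets, another probe set was called in the opposite direction.

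**Figure D3:**
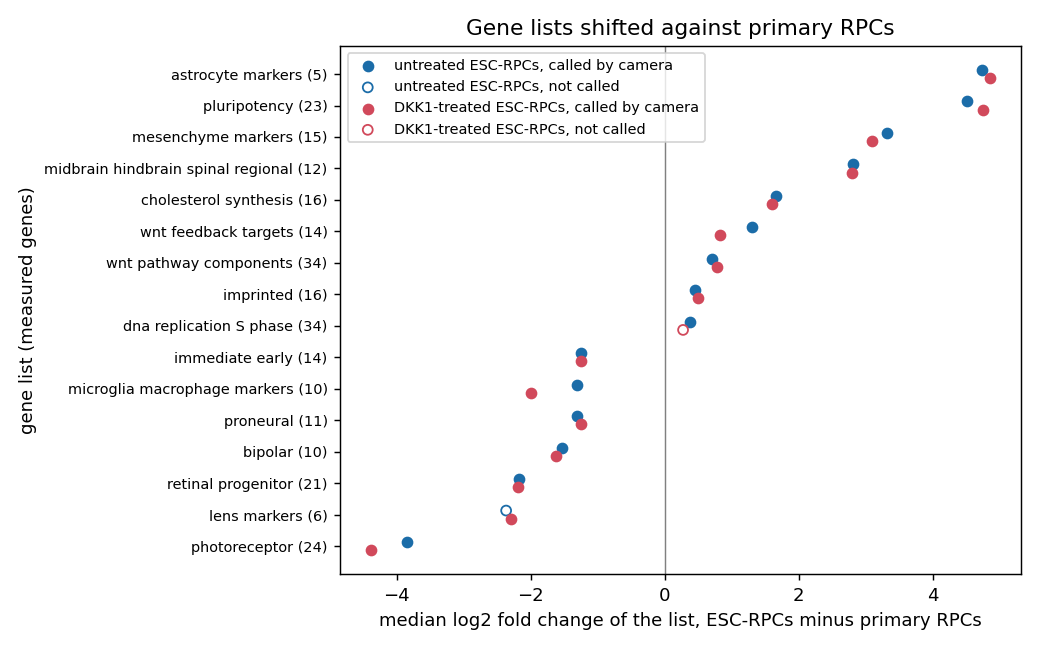
Median log2 fold change of gene lists in DKK1-treated and untreated ESC-RPCs minus primary RPCs, with the number of measured genes in parentheses; filled points were called by camera and open points were not. The pluripotency list lies at 4.51 for untreated cells, and the photoreceptor list at -3.84.

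The third comparison set DKK1-treated ESC-RPCs against primary RPCs, the remaining pair of groups. Most of the pluripotency genes measured were higher in DKK1-treated cells, and most of the photoreceptor genes were lower. Zfp42 was at least 80.7-fold higher at 3837 ± 406, and Nanog at least 49.1-fold higher at 2331 ± 213. Crx was at least 91.5-fold lower at 8.29 ± 4.60, and Rax at least 82.2-fold lower at 12.5 ± 16.0. Axin2, the Wnt feedback gene, measured 608 ± 39.7 against 245 ± 21.7 in primary cells.

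Of 23 pluripotency genes, 21 rose in DKK1-treated cells and 1 fell (median 4.75, or 3.64 with bounds, camera adjusted p = 5.38e-12; adjusted p = 0.0756 with an estimated correlation). Fbxo15 was at least 30.8-fold higher, Tdgf1 at least 19.6-fold, S100g at least 27.3-fold, Morc1 at least 18.1-fold, Trap1a at least 36.5-fold and Serpinb1a at least 21.9-fold. Of 24 photoreceptor genes, 22 fell (median -4.38, or -3.04 with bounds, adjusted p = 1.22e-10; adjusted p = 0.0756 with an estimated correlation), such as Neurod1 at 1204 ± 241 against 16847 ± 1667. Of 21 retinal progenitor genes, 16 fell and 4 rose (median -2.19, adjusted p = 3.44e-05; adjusted p = 0.0756 with an estimated correlation). Six6 measured 63.2 ± 27.7 against 4386 ± 440.3 and Pax6 1255 ± 210.5 against 10035 ± 1063, while Hmx1 was at least 45.9-fold lower and Kcne2 at least 7.13-fold lower. Pdc was at least 171-fold, Dapl1 at least 122-fold and Aldh1a1 at least 64.6-fold lower, and Xist fell from 11668 ± 1030.2 to 67.7 ± 5.44. All 6 measured lens markers fell (median -2.29, or -1.52 with bounds, adjusted p = 0.0218; adjusted p = 0.425 with an estimated correlation), such as Cryaa, a lens crystallin, at least 7.54-fold lower. In untreated cells 3 of these 6 fell (adjusted p = 0.0927), and the difference between the 2 comparisons was not tested.

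Of 14 Wnt feedback targets, 10 rose and 2 fell against primary cells (median 0.83, adjusted p = 0.00632; adjusted p = 0.41 with an estimated correlation). Lef1 measured 744 ± 37.6 against 508 ± 300.3 (adjusted p = 0.0757 in limma), and Ccnd1 fell from 12525 ± 2968 to 3711 ± 698. Of 34 Wnt pathway components, 22 rose and 5 fell (adjusted p = 0.00221; adjusted p = 0.0842 with an estimated correlation). All 16 cholesterol synthesis genes rose (median 1.60, adjusted p = 2.34e-08; adjusted p = 0.286 with an estimated correlation), such as Cyp51 at 3675 ± 317 against 1166 ± 132. Of 15 mesenchyme markers 13 rose and 1 fell (adjusted p = 4.74e-08; adjusted p = 0.189 with an estimated correlation), and all 5 astrocyte markers rose (adjusted p = 2.86e-05; adjusted p = 0.0842 with an estimated correlation). Of 12 midbrain, hindbrain and spinal genes 9 rose and 1 fell (adjusted p = 0.000668; adjusted p = 0.0842 with an estimated correlation), and of 16 imprinted genes 9 rose and 2 fell (adjusted p = 0.0267; adjusted p = 0.136 with an estimated correlation). The forebrain genes moved as in untreated cells, except that Tbr1 fell here (adjusted p = 0.0233 in limma), and camera did not call their list. Falls were counted for 12 of 14 immediate early genes (adjusted p = 0.000279; adjusted p = 0.0842 with an estimated correlation) and 8 of 11 proneural genes (adjusted p = 0.000679; adjusted p = 0.189 with an estimated correlation). They were also counted for 7 of 10 bipolar cell genes (adjusted p = 0.00744; adjusted p = 0.0895 with an estimated correlation) and 6 of 10 microglia and macrophage markers (adjusted p = 0.00744; adjusted p = 0.333 with an estimated correlation). Of 34 DNA replication genes 12 rose and 1 fell (adjusted p = 0.0542), of 34 mitosis genes 2 rose and 11 fell (adjusted p = 0.0687), and of 27 proto-oncogenes and oncofetal genes 11 rose and 10 fell (adjusted p = 0.89). Mki67 fell from 6349 ± 412 to 3885 ± 582.

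In limma, 7034 of 13320 genes (52.8%) changed between DKK1-treated ESC-RPCs and primary cells, 3463 higher and 3571 lower, and 2821 by at least 2-fold. With arrays set to one median the balance turned, to 3514 higher and 3022 lower. Camera called 15 of 35 lists, 8 higher and 7 lower, 0 with an estimated correlation, while fry called 28. Adjusted over the list alone, 11 Wnt feedback targets rose, 7 Wnt pathway components fell and 11 DNA replication genes rose, and the other counts given were the same. Both ESC-RPC groups shared 3177 genes called higher and 3211 called lower than in primary cells, where independent lists would share 905 and 959. None was called in opposite directions. In 20 simulations in which no group differed from the controls, at most 0 genes were shared. Unchanged groups leave hardly any called genes to share, so this 0 cannot show how much of the overlap comes from shared controls. Log2 differences correlated at 0.981 across genes against 0.501 in the simulations, with a covariance of 1.55 against 0.0401. At the fitted spread, noise in the shared controls gave only the covariance of 0.0401, which argues against such noise as the main source of the 1.55. A deviation common to all 3 primary arrays was not simulated. These arrays are too few to split, so part of the shared calls may still come from such a deviation.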

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

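The tests of array scaling, signal near background, other probe sets, stem cell content and Y-linked genes were chosen after the results were seen, as was the blocked fit of 6 arrays, while the counts over other splits of the arrays were planned.

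Probe sets without a single gene name were not part of the comparisons, and they too differed from the primary cells. Of 4279 such probe sets tested with limma, 834 were higher in untreated and 824 in DKK1-treated ESC-RPCs than in primary RPCs. In all, 1760 and 1804 of them changed, or 41.1% and 42.2%, against 48.6% and 48.5% of probe sets with a gene name. Between DKK1-treated and untreated cells 0 of them changed in limma, with a smallest adjusted p of 0.17. Groups of 3 arrays are too small to test for a single array far from the others.

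With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. For genes changed by DKK1, 10 of the 10 splits gave as many as the real 0, and the highest other split gave 0 by limma. No split could give fewer, so this count tests nothing. For lists, 4 of the 10 gave as many as the real 8, and the highest other gave 17. If the numbers pair these arrays, which the labels do not state, the 4 splits that part all 3 pairs apply. Among these 4 the real one gave 8 lists and the others 0, 0 and 1. The splits with 17, 13 and 10 lists leave a pair together. These 4 splits are too few to judge. Against primary cells, 1 of the 10 splits gave as many genes as the real 7060 for untreated cells and 1 of the 10 as many as the real 7034 for DKK1-treated cells, and the highest other gave 0 in both. For lists against primary cells, 2 of the 10 splits gave as many as the real 15 for untreated cells (highest other 17) and 3 of the 10 for DKK1-treated cells (highest other 18). In the blocked fit of 6 arrays, 1 of the 4 splits that part all 3 pairs gave as many genes as the real 65, the highest other gave 0, and 4 splits are also too few.

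Wnt feedback targets had lower intensities after DKK1, with a list median of -0.23, which was -0.12 without DKK1-treated replicate 2 and -0.13 without untreated replicate 3. Array scaling is argued against as the whole source, since quantile normalisation left the median at -0.243086 (camera adjusted p = 0.000161). Signal near background is argued against too, since 11 members passed the stricter filter with a median of -0.244632 (adjusted p = 0.000142). Only 1 of the 10 splits gave a median as far from 0, and the highest other was 0.197206 (0.141 among splits that part all 3 pairs), but 10 splits are too few to judge. An effect of DKK1 on Wnt signalling is a candidate explanation that stays open, as does a correlated shift of these genes between cultures, since the adjusted p was 0.637 with an estimated correlation.

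Pluripotency transcripts were higher in Sox1-sorted ESC-RPCs than in primary RPCs. For 7 of the 21 genes called higher, the 8 other kept probe sets were all called higher too. A probe set dim in primary cells, such as those used for Dppa2, Gdf3, Lin28a and Sall4, passes the filter only through ESC-RPC arrays. The filter thus partly fixed this outcome, which cannot decide whether probe sets cross-hybridised. The other genes called higher, among them Nanog, Zfp42 and Dppa5a, had no other kept probe set, so probe sets could not be compared there. Probe sets removed by the filter were not compared. Undifferentiated stem cells that came through the sort could bring these transcripts, and so could retained expression within the progenitors. All 23 listed genes lay above the 40th percentile on the 3 untreated arrays, with Dppa5a highest among those named at 10411, which both explanations allow, so they cannot be told apart in these bulk profiles. The list contains 2 genes that another list also holds, Lin28a and Sall4.

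Xist was high in primary RPCs and low in both ESC-RPC groups. Primary RPCs may come from pups of both sexes pooled, which would leave Y-linked transcripts present at a lower level than in male cells. Of 3 measured Y-linked genes, 2 were lower in primary than in untreated cells while above the 40th percentile there, Eif2s3y by 0.95 and Uty by 1.15 in log2. Kdm5d went the other way, with a log2 difference of -2.35 for untreated minus primary cells on its 1 kept probe set. Its probe sets removed by the filter read 2.73 in untreated against 2.80 in primary cells, and 30.8 against 19.2. On the probe sets used, each primary array held Xist at 10985 to 12853 together with Eif2s3y at 530 to 981 and Uty at 118 to 217. These lie above the 40th percentiles of 44.7 to 52.9, as cells of both sexes on each array would give. Other probe sets of Eif2s3y and Uty read lower. The sexes of the pups and of the stem cell line are not in the labels, so pooling stays open. A difference in cell type between the groups was not tested.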

How the results depend on the processing

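The blocked fit of 6 arrays with its alternatives, and the lists with arrays set to one median, were chosen after seeing the data; the other alternatives were planned. Between DKK1-treated and untreated cells, the count of 0 genes held under quantile normalisation, arrays set to one median, added 32, both filter settings, the mean of probe sets, tests per probe set, the 2-fold threshold and each array left out. Without the intensity trend limma called 1 gene, Zfp429, named after its values were seen (19.6 against 1.75). The replicate block on all 9 arrays gave 0, 7048 and 7043 genes and 9, 15 and 15 lists in the 3 comparisons, each within 1.5 times the count without it. The block on the 6 arrays taken as paired gave 65 genes. Its alternatives gave 32 (quantile), 21 (no filter), 0 (mean of probe sets) and 1 (2-fold, the unnamed transcript 2700046A07Rik). They also gave 0 (no trend), 0 (no block) and 8 to 213 with a pair left out. With the mean of probe sets, 59 of the 65 kept their sign.

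The 8 lists became 5 with the mean of probe sets, 0 with an estimated correlation, 0 by fry and 5 to 14 with an array left out. The Wnt target median of -0.23 had adjusted p-values of 0.637 with an estimated correlation and 0.91 by fry, and at most 0.0335 with an array left out (medians -0.30 to -0.12). The DNA replication list turned direction in camera without DKK1-treated replicate 2 (median -0.00689; -0.18 to -0.01 over all arrays left out). Against primary cells, tests per probe set gave 13798 and 13823 calls for untreated and DKK1-treated cells, and the 2-fold threshold 2770 and 2821. List counts were 0 and 0 with an estimated correlation and 27 and 28 by fry. Leaving out an array gave 5942 to 7286 and 5931 to 7308 genes. The distance difference lay between 0.00257 and 0.018 with an array left out, and was 0.00235 with no filter and 0.0045 with the stricter one. Beyond fewer genes or arrays, the cause was not tested. Over all settings of the lists other than the Wnt targets after DKK1, 1348 results kept their status as called or not called. A further 58 became stronger, 65 weaker and 1 turned, the DNA replication list above. For named genes the counts were 7477, 30, 21 and 0. Results called in neither setting count as kept, whatever their sign. Of the 7477, 2473 compare DKK1-treated with untreated cells, where no gene had a call to lose. Signal near background limits genes with intensities under the 40th percentile, 44.7 to 52.9 by array.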

Other observations

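The gene families below were chosen after the results were seen, with 225 families formed from shared name stems and tested by camera.

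Collagen genes were higher in ESC-RPCs than in primary RPCs. Of 34 measured, 23 rose and 6 fell in untreated cells (median 1.36, adjusted p = 0.00346; adjusted p = 0.996 with an estimated correlation), and 25 rose and 6 fell in DKK1-treated cells. The direction held under quantile normalisation (median 1.36) and with arrays set to one median (1.43). Large ribosomal subunit genes also differed: of 23 measured, 20 rose in untreated cells against primary cells (median 0.38, or 0.11 after quantile normalisation, adjusted p = 7.42e-06; adjusted p = 0.996 with an estimated correlation). After DKK1 they had a median of -0.11 against untreated cells (adjusted p = 2.69e-08; adjusted p = 0.99 with an estimated correlation), and of -0.02 after quantile normalisation. Small subunit genes turned from a median of -0.05 to 0.01 after quantile normalisation in the same comparison.

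Kdr, a receptor for vascular endothelial growth factor, fell from 6063 ± 1113 in primary RPCs to 74.4 ± 6.45 in untreated ESC-RPCs, while 4 of the 7 endothelial markers did not pass the test. Of 15 amacrine and horizontal cell genes 4 rose and 6 fell, and of 15 ganglion cell genes 4 rose and 9 fell in untreated cells against primary cells. Of 16 Müller glia genes 6 rose and 7 fell in the same comparison.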
